A study of Mus musculus with 9 samples.

How the data were processed

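Nuclear RNA was read in 9 libraries of snap-frozen mouse lung, 3 per group, per the labels: Nox (replicates 1 to 3), Su/Hx+LNA-ctrl (4 to 6) and Su/Hx+LNA-224 (7 to 9). Numbers follow the order of the library names. The labels do not state that the 3 libraries of a group come from separate animals. If they do not, the p-values measure only the spread between these samples. Sex, age, dose, timing of treatment, batch and time of day of collection are not given in the sources used here. The deposited values are UMI counts per gene and barcode, made by the authors with Cell Ranger 8.0.1 per the file headers, on mm10 per the labels, from a 3' assay of the third version per the labels. Annotation release, counting of intron reads and the settings for calling cells are not given in the sources used here. All libraries hold the same 32285 genes. Of these, 32158 were found in GENCODE vM21 (GRCm38), and 20855 have an annotated 3' UTR.

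Barcodes with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept (7274 barcodes failed the mitochondrial limit and 39 the gene limit). Scrublet was run per library with an expected rate of 10%. Its automatic threshold was used when it removed 0.5 to 40% of barcodes (7.85 to 19.3% in 7 libraries). In Nox 3 and LNA-ctrl 5 it did not, and the highest-scoring 0.8% per 1000 barcodes were removed instead. This took out 28.0% of barcodes in Nox 3 and 27.0% in LNA-ctrl 5, more than in any other library. The libraries had 73161633 to 162000915 UMIs, 17771 to 27163 nuclei and median UMIs per nucleus of 2089 to 3271.5. Median UMIs ranged over 2121 to 2943 in Nox, 2089 to 3082 in LNA-ctrl and 2550.5 to 3271.5 in LNA-224, and overlap between the groups. Total UMIs part Nox (82624664 to 105044606) from LNA-224 (112601321 to 140738950), with LNA-ctrl spanning both.

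Clusters were made without integration from 4000 nuclei per library (scanpy 1.11.5, 2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1.5 with leidenalg 0.10.2), and each other nucleus took the class of most of its 15 nearest sampled nuclei. Clusters were named from marker lists for 33 classes, written before the data were examined. Clusters 0 and 1, with few UMIs per nucleus and no class of their own, were kept apart as low-UMI barcodes and read as a measure of free RNA. They part by group: cluster 0 held 30.2, 5.01 and 31.5% and cluster 1 held 0.410, 32.5 and 1.08% of kept barcodes in Nox, LNA-ctrl and LNA-224. The measure thus differs in kind between LNA-ctrl and the other groups. Low-UMI barcodes made up 30.6 ± 15.1, 37.5 ± 9.28 and 32.6 ± 6.08% of kept barcodes in Nox, LNA-ctrl and LNA-224 (mean ± SD, n = 3), and clusters without a name 0.540, 1.62 and 1.17%. All-nuclei values include both. Class shares are percent of nuclei in named classes.

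Counts were summed per library over all nuclei and within each class with at least 30 nuclei in every library. Genes were filtered by filterByExpr and scaled by TMM, and 1 quasi-likelihood fit with a coefficient per group was made over all 9 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3). LNA-ctrl was compared with Nox, LNA-224 with LNA-ctrl and LNA-224 with Nox. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a class. The SE of an edgeR log2 fold change was derived from the test, as its absolute value over the square root of the quasi-likelihood F. General capillary, aerocyte and arterial endothelial, smooth muscle and alveolar fibroblast nuclei were described gene by gene, and the remaining 19 classes as one count. Camera tested 28 gene lists with at least 5 tested members, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data, and adjusted p over 155 tests per comparison. Class shares were tested by an exact permutation of the between-group sum of squares. Seed-site genes have a 7-base or longer match to the miR-224-5p seed in the 3' UTR, and were matched one to one with genes without a match by level and 3' UTR length. In the simulations beside the opposite-sign shares, 100 sets of LNA-224 libraries without a change were drawn.

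The comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule names, per comparison, the 5 highest and 5 lowest log2 fold changes over all nuclei and the 2 highest and 2 lowest in each of 5 classes, among called genes with an average log2 CPM of at least 4 and no overlap between groups, leaving out predicted genes, haemoglobin and immunoglobulin genes and markers of other classes. It always names Bmpr2, Acvrl1, Eng, Smad1, Smad4, Smad5, Smad6, Smad7, Smad9, Id1, Id2, Id3, Gabre and Mir224 over all nuclei and in general capillary nuclei, and up to 4 members of each list with the smallest p. For genes named by the fold-change rule, libraries lying apart is thus a condition of selection and not added evidence where it is stated below. Genes counted over all classes, such as Chil3, the clock genes and Cyp1a1, were chosen after their values were seen. A gene with 0 counts in a group is given as a fold against a floor of 3 counts over the group.

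The tests were tried on simulated data with 200 genes changed 2- or 4-fold. Over all nuclei edgeR recovered 51.0% of the 2-fold and 90.9% of the 4-fold genes for LNA-ctrl against Nox (21134 genes, 7.84% of calls false), and 54.5% and 88.8% for LNA-224 against LNA-ctrl (21153 genes, 4.73%). In general capillary nuclei it recovered 52.0% and 94.9% (15598 genes, 3.97%), then 57.0% and 88.8% (15622 genes, 5.26%), and in smooth muscle nuclei 24.5% and 80.8% (8703 genes, 5.45%), then 41.0% and 96.9% (8593 genes, 8.11%). In aerocytes, arterial and alveolar fibroblast nuclei 2-fold changes were recovered at 52.6 to 63.0%. False calls by DESeq2 1.42.0 came to 21.9% and 27.0% over all nuclei, 10.5% and 13.95% in general capillary nuclei and 3.03% and 3.01% in smooth muscle nuclei. Camera called a list shifted by 0.5 but 2 of 27 lists in all when only that 1 was shifted, a seed-site shift of 0.2 came back as 0.20, and 89.5% of differences between capillary classes were found. Simulated genes were drawn independently, so the trial does not show how camera behaves where genes are correlated.

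The alternatives were DESeq2, RLE size factors, no low-count filter, a fit of 2 groups only, at least 1000 UMIs, doublets kept, Leiden resolution 0.8, markers of other classes left out, other camera settings and fry, the 500 lowest p in place of called genes, 8-base seed sites, and each library left out in turn. Mature miR-224 was not analysed here, nor reads, intron counts or haemodynamic values. Results for 2 genes are not reported here. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, matplotlib 3.10.9 with data.table (1.17.8) in R.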

Results

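Nuclei from 9 mouse lung libraries were compared in 3 groups of 3: normoxia (Nox, replicates 1 to 3), Su/Hx with a control LNA (LNA-ctrl, replicates 4 to 6) and Su/Hx with an LNA against miR-224 (LNA-224, replicates 7 to 9). Su/Hx is the usual short name of the sugen and hypoxia model of pulmonary hypertension, and an LNA is a locked nucleic acid oligonucleotide. The Nox label names no LNA, so LNA-ctrl against Nox does not separate Su/Hx from the control LNA. The libraries held 264038 barcodes and 1021487779 UMIs, and 212429 nuclei were kept, with 66014 from Nox, 72570 from LNA-ctrl and 73845 from LNA-224. Libraries held from 73161633 to 162000915 UMIs, both extremes in LNA-ctrl. The LNA-ctrl libraries differed most from one another: pairs of them gave chi-square values per degree of freedom of 103, 225.0 and 311, against 37.9 to 54.1 in Nox and 37.2 to 57.6 in LNA-224. Ddx3y lay at 94.9 to 116 CPM in every library and Xist at no more than 2.21 CPM, the pattern of male lungs. Clusters were named from marker genes, and every class name below therefore stands for nuclei that resemble that class.

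Over all nuclei, Ahrr, Cyp1b1 and Cyp1a1 had the largest rises in LNA-ctrl against Nox among genes that pass the naming rule. Ahrr (ENSMUSG00000021575, chr13:74211118-74292331, GRCm38) rose from 0.677 ± 0.192 to 61.1 ± 8.17 CPM (log2 fold change 6.497 ± 0.32 SE), Cyp1b1 (ENSMUSG00000024087, chr17:79701537-79715061) by 5.78 ± 0.31 and Cyp1a1 by 5.73 ± 0.23, from 2.93 to 155 CPM. Their adjusted p-values were 1.4e-05, 2.6e-05 and 3.9e-06 (edgeR quasi-likelihood, Benjamini-Hochberg, n = 3 and 3), with all 3 libraries of each group on the same side. Lrrc3b rose by 3.66 ± 0.26 and Lama1 by 3.65 ± 0.31. The largest falls by the same rule were of the myeloid genes S100a9, from 82.1 to 5.05 CPM (-4.01 ± 0.54), Il1b (-3.37 ± 0.47) and Csf3r (-2.97 ± 0.30), with Hspb1 (-2.44 ± 0.42) and Slc6a2 (-2.27 ± 0.29) next. The 3 myeloid genes are among the top 10 genes of the neutrophil cluster, and the share of neutrophils went from 5.21 to 0.716% of nuclei in named classes, so these falls are not separated from that change in composition. Nor is that of Hspb1, a top 10 gene of low-UMI cluster 0, which held 30.2% of kept barcodes in Nox and 5.01% in LNA-ctrl and is part of the all-nuclei values. All of these 10 genes separated the groups without overlap, which the naming rule requires. The call of Hspb1 ended without LNA-ctrl 4 (edgeR adjusted p 0.0656).

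In the BMP pathway, over all nuclei, Eng (ENSMUSG00000026814) fell from 215 to 94.1 CPM (-1.19 ± 0.11, edgeR adjusted p 0.000805) and Smad6 by 0.86 on the log2 scale (± 0.20, adjusted p 0.0344), while Smad5 rose by 0.64 ± 0.14 (adjusted p 0.0294). All 3 libraries of each group lay on the same side for these 3 genes. Smad6 was no longer called without Nox 1, Nox 2, LNA-ctrl 6 or LNA-224 9 (adjusted p 0.0551 to 0.120), nor Smad5 without Nox 1, Nox 2 or Nox 3 (0.0775 to 0.101). Bmpr2 (-0.23 ± 0.15), Acvrl1 (0.22), Smad1 (0.33), Smad4 (0.03), Smad7 (0.14), Smad9 (0.01), Id1 (-0.62), Id2 (-0.18) and Id3 (-1.02 ± 0.29) were not called. Gabre, the gene whose span holds Mir224 (chrX:72261031-72261112), lay at 21.5 ± 1.07 CPM in Nox, 14.9 ± 2.87 in LNA-ctrl and 17.2 ± 1.94 in LNA-224, without a call.

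Of 21303 genes tested over all nuclei, 685 were higher and 617 lower in LNA-ctrl than in Nox (1302 together), and 1297 of these separated the groups without overlap. Groups of 3 and 3 were separated without overlap for 27.8% of all tested genes, where chance alone gives 10%. The count depended on single libraries. It was 567 without Nox 1, 516 without Nox 2, 675 without Nox 3, 3128 without LNA-ctrl 5, 828 without LNA-ctrl 6 and 860 without LNA-224 9.

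In general capillary endothelial nuclei, 1002 of 15787 genes were higher and 703 lower in LNA-ctrl. Cyp1b1 rose from 0.498 ± 0.081 to 415 ± 107 CPM (9.68 ± 0.46, edgeR adjusted p 3.4e-06) and Ahrr from 0.786 ± 0.251 to 213 ± 17.97 CPM (8.08 ± 0.32, 2.5e-07). Slc16a9 fell from 212 ± 27.3 to 19.9 ± 8.38 CPM (-3.45 ± 0.26, 2.5e-05) and Pknox2 from 424 ± 217 to 53.3 ± 18.8 CPM (-2.99 ± 0.41, 0.00184), each with all 3 libraries of both groups apart. The class is split over clusters by treatment. Cluster 6 held 2602 to 2952 nuclei per Nox library and 27 to 177 per Su/Hx library, and cluster 3 held 52 to 153 and 2824 to 3571. Cluster 6 had a mean log2 fold of 2.26 for the class markers, with 9 of 10 detected. Cluster 3 had 1.39 with 5 of 10, close to the limit of 1.3 for a name. Changes within cells are thus not separated from a difference in the nuclei given this name. The count of 1705 was 1029 without Nox 2 and 992 without Nox 3.

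In this class Bmpr2 (ENSMUSG00000067336, chr1:59763400-59879014) fell from 2402 ± 278 to 1516 ± 164 CPM (-0.66 ± 0.13, edgeR adjusted p 0.00607), Eng from 845 ± 25.9 to 293 ± 47.4 CPM (-1.53 ± 0.13, 2.5e-05) and Smad6 from 740 ± 109 to 273 ± 38.8 CPM (-1.44 ± 0.20, 0.000845). Bmp6 fell by 1.38 on the log2 scale (0.000217), Smad5 rose by 0.95 ± 0.15 (0.00174) and Bmp2 rose from 0.946 to 9.87 CPM (3.40 ± 0.42, 0.000388). In all 6 of these genes the 3 libraries of each group lay apart. Id3 also fell (-0.84 ± 0.21, edgeR adjusted p 0.0248, all 3 libraries apart), a call that ended without Nox 1, Nox 2, Nox 3 or LNA-ctrl 6 (0.0616 to 0.0879). Id1 (-0.43), Id2 (-0.16), Smad1 (0.01), Smad4 (-0.04), Smad7 (0.02), Smad9 (-0.73), Acvrl1 (0.15) and Gabre (0.01) were not called. The levels of the named genes per library are drawn with Ahrr, Cyp1b1, Eng, Smad6 and Bmpr2 among them.

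**Figure D1:**
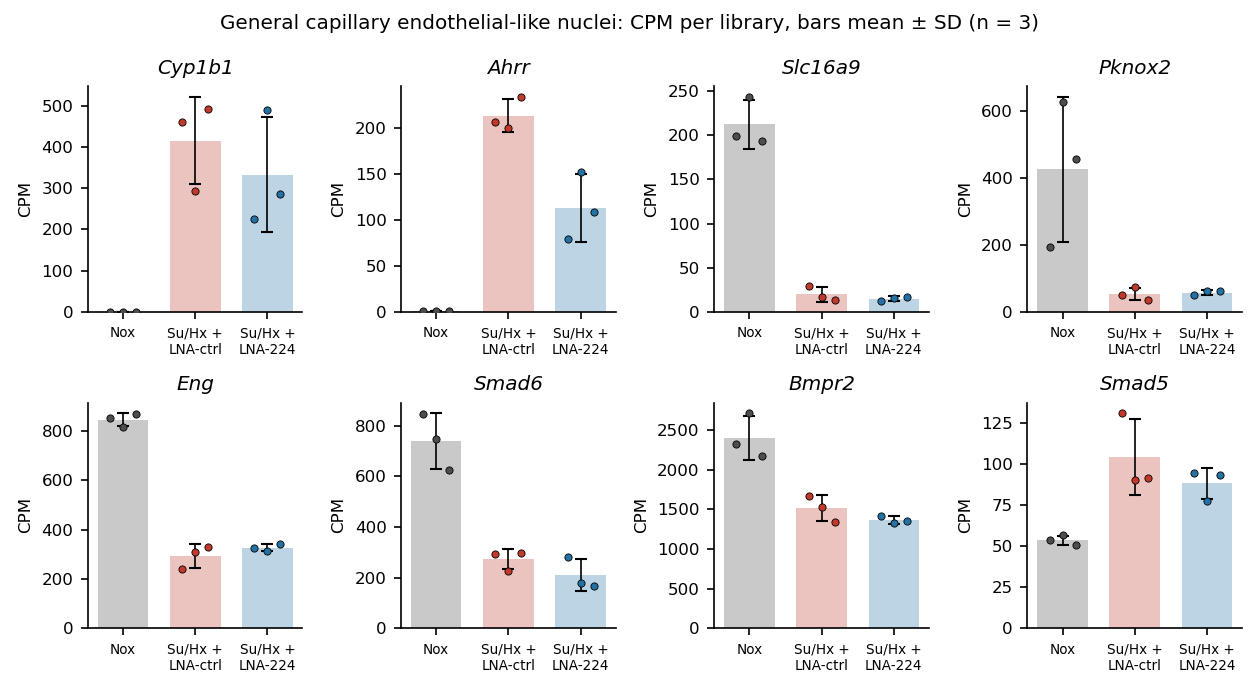
CPM of 8 genes in general capillary endothelial nuclei by group (Nox, LNA-ctrl, LNA-224), with points for libraries and bars for mean ± SD (n = 3). Eng lies at 845, 293 and 327 CPM on average.

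Among 31 hypoxia-induced genes in general capillary nuclei, 12 were called higher and 0 lower (median log2 fold change 0.45, camera adjusted p 0.000131, 0.351 with estimated correlation). Vldlr rose by 2.89 ± 0.19, Bnip3 by 1.61 ± 0.21, Ndrg1 by 1.43 ± 0.16 and Egln3 by 4.40 ± 0.66, from 0.2499 to 5.63 CPM. BMP-SMAD target genes lay lower as a list, with 2 of 18 called higher and 6 lower (median -0.39, camera adjusted p 0.0120, 0.474 with estimated correlation), among them Hey1 (-2.53 ± 0.34), Smurf2 (-0.71 ± 0.11), Skil (-0.69 ± 0.12) and Stab1 (-1.30 ± 0.12). Adjusted over the list alone, 13 hypoxia genes were higher and 2 lower, and 2 BMP-SMAD targets were higher and 8 lower. Immediate-early and heat-shock genes gave 1 higher and 9 lower of 29 (median -0.90, 0.000272, 0.474 with estimated correlation), interferon-response genes 1 higher and 7 lower of 31 (median -0.31, 0.000522, 0.659 with estimated correlation), with Ifi44 at -1.25 ± 0.14. NF-kB genes gave 0 higher and 5 lower of 18 (median -0.15, 0.0206, 0.420 with estimated correlation). Hspb1 and Hsp90aa1, both lower, were not called without LNA-ctrl 4 (edgeR adjusted p 0.0778 and 0.0780). Hspb1 is a top 10 gene of low-UMI cluster 0, so its fall is not separated from free RNA.

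Extracellular matrix genes (36 tested, 4 called higher and 2 lower, median 0.33, camera adjusted p 0.00830, 0.732 with estimated correlation), antigen presentation genes (16, 2 and 0, 0.36, 0.0146, 0.732), lipid and fatty acid metabolism genes (26, 5 and 3, 0.43, 0.0227, 0.420) and surfactant genes (11, 3 and 0, 0.40, 0.0163, 0.732) lay higher in the same class. Col15a1 rose by 2.37 ± 0.22, Timp3 by 1.21 ± 0.18, Ciita from 50.8 to 203 CPM (1.996 ± 0.21) and Pparg by 1.97 ± 0.33, and Vcan fell by 1.48 on the log2 scale (± 0.26). The circadian clock list moved up (8 higher and 2 lower of 20, median 0.44, camera adjusted p 0.0465, 0.420 with estimated correlation), with Nr1d1 at 2.10 ± 0.21, Nr1d2 at 1.81 ± 0.20 and Ciart at -1.73 ± 0.18. Haemoglobin genes had a median of -4.38 with 0 of 5 called (camera adjusted p 0.00677, 0.572 with estimated correlation). Surfactant and haemoglobin genes belong to other cells, so their levels here can come from free RNA.

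No other list moved in general capillary nuclei in this comparison. Camera adjusted p-values were 0.605 for BMP ligands and receptors (1 higher and 4 lower of 22), 0.917 for SMAD transducers (3 and 3 of 14), 0.336 for TGF-beta genes, 0.827 for heritable pulmonary hypertension genes, 0.796 for VEGF and angiogenesis genes (7 and 8 of 29) and 0.4001 for vasoactive genes (4 and 7 of 29). They were 0.160 for smooth muscle contractile genes, 0.705 for endothelial-mesenchymal transition genes, 0.153 for cell cycle genes, 0.705 for apoptosis and p53 genes, 0.197 for glucocorticoid response genes, 0.647 for alveolar stress genes and 0.187 for regenerative capillary genes. They were 0.917 for reported miR-224 targets, 0.225 for quality genes and 0.689 for sex-linked genes. The sign of the median (0.05 and -0.04) is opposite to the direction of the test for SMAD transducers and reported miR-224 targets, and median and mean differ in sign for vasoactive genes (-0.04 and 0.02) and alveolar stress genes (-0.08 and 0.06), as for sex-linked genes (-0.07 and 0.00). Single genes within these lists moved all the same. Dll4 fell from 65.3 to 8.70 CPM (-2.89 ± 0.24), Esm1 by 3.71 on the log2 scale, Vegfc rose from 372 to 1383 CPM (1.89 ± 0.20), Tgfbr2 by 1.39 ± 0.14, Ntrk2 from 68.9 to 628 CPM (3.19 ± 0.41), Prkg1 fell by 1.59 on the log2 scale and Cacna1c rose by 2.58 ± 0.21.

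In aerocyte endothelial nuclei, Ahrr had 0 counts in all 3 Nox libraries and 142 ± 12.1 CPM in LNA-ctrl, at least 286-fold higher (edgeR adjusted p 3.6e-10), and Cyp1b1 rose by 9.71 ± 0.46. Hpgd fell from 916 to 74.7 CPM (-3.59 ± 0.26, edgeR adjusted p 4.3e-06) and Fibin by 3.20 on the log2 scale (± 0.27, 4.3e-06), with all 3 libraries of each group apart. The vasoactive receptor genes Ednrb (559 to 233 CPM, -1.26 ± 0.13), Calcrl (5861 to 2714 CPM, -1.11 ± 0.16), Ramp2 (-1.83 ± 0.25) and Htr2b (-1.97 ± 0.30) fell, 7 of 23 vasoactive genes being called lower and 1 higher (median -0.32, camera adjusted p 0.00930, 0.420 with estimated correlation). The p53 targets Eda2r (2.52 ± 0.23) and Zmat3 (1.44 ± 0.21) rose. In all, 443 of 11049 genes were higher and 370 lower (813 together, 490 without Nox 2 and 456 without Nox 3).

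In arterial endothelial nuclei, Ahrr rose by 9.53 ± 0.50 (edgeR adjusted p 5.1e-09) and Cyp1b1 from 1.75 to 743 CPM (8.64 ± 0.38, 5.8e-10), while Sele fell from 83.3 to 0.811 CPM (-6.34 ± 0.64, 1.9e-05). Sgcz, at 50.6 ± 17.6 CPM in Nox, had 0 counts in LNA-ctrl, at least 70.5-fold lower (edgeR adjusted p 2.5e-07). Each of these 4 genes had all 3 libraries of both groups apart. Fbln5 rose from 134 to 616 CPM (2.20 ± 0.15), Eln from 514 to 1533 CPM (1.58 ± 0.17) and Lox by 1.60 ± 0.35, with Col15a1 at 3.64 ± 0.38. Edn1 rose by 1.08 ± 0.17, and Ace (-1.38 ± 0.18), Gucy1b1 (-1.63 ± 0.23) and Prkg1 (-1.93 ± 0.19) fell, 8 of 21 vasoactive genes being called lower and 2 higher (median -0.33, camera adjusted p 0.00169, 0.351 with estimated correlation). In all, 639 of 10870 genes were higher and 610 lower.

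In smooth muscle nuclei, several contractile and stress genes fell. Cnn1 fell from 678 to 77.7 CPM (-3.06 ± 0.32, edgeR adjusted p 0.000123), Des by 1.52 (± 0.24) and Myl9 by 1.12 (± 0.22) on the log2 scale and Actc1 from 630.3 to 39.8 CPM (-3.92 ± 0.43, 0.00106), with all 3 libraries of both groups apart. Of 20 contractile genes 7 were called lower and 0 higher (median -0.73, camera adjusted p 1.0e-07, 0.420 with estimated correlation), and adjusted over the list alone 11 were lower and 1 higher. Atf3 fell from 137 to 6.68 CPM (-4.22 ± 0.47), Jun from 206 to 30.7 CPM (-2.79 ± 0.31), Errfi1 by 2.72 and Hspa1a by 6.42 (± 0.81) on the log2 scale, 15 of 26 immediate-early and heat-shock genes being lower (median -1.63, camera adjusted p 3.5e-27, 0.223 with estimated correlation). Cyp1a1 rose by 5.97 ± 0.59, to 0.9865 times the level expected from free RNA, so the rise is not separated from free RNA. Ahrr was at least 11.3-fold higher (edgeR adjusted p 0.0162), a call that ended without Nox 3 or LNA-ctrl 4 (0.0588 to 0.0622). In all, 107 of 8923 genes were higher and 173 lower (280 together, 139 without Nox 3, 124 without LNA-ctrl 4 and 139 without LNA-ctrl 6). The class is small (58 to 206 nuclei per library), and the cluster named myofibroblast has a higher mean log2 fold for smooth muscle markers (3.95) than for its own (2.81), against 4.30 for smooth muscle markers in the smooth muscle cluster. Its share went from 0.512 to 0.960% of nuclei in named classes. Vsnl1 (5.35 to 55.9 CPM) and Kcnq5 (251 to 623 CPM) rose in it, while others of the top 10 pericyte cluster genes were not called. Igkc, of low-UMI cluster 0, fell from 237 to 10.6 CPM. The falls above are thus not separated from a change in the nuclei and free RNA that make up the class.

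The genes beside miR-224 were also lower in LNA-ctrl smooth muscle nuclei, 2 of 2 tested members of that list, which is too short for camera. Gabre lay at 93.9 CPM in Nox, 38.3 in LNA-ctrl and 47.2 in LNA-224 (-1.22 ± 0.31 in LNA-ctrl, edgeR adjusted p 0.0354) and Gabra3 at 236, 98.1 and 125 CPM (-1.23 ± 0.26, 0.0151), all 3 libraries of Nox and LNA-ctrl apart for both. These 2 genes were chosen after their values were seen, and the calls are weak. That of Gabre ended without Nox 1, Nox 2, Nox 3, LNA-ctrl 4, LNA-ctrl 6 or LNA-224 8 (edgeR adjusted p 0.0562 to 0.113) and that of Gabra3 without Nox 3 or LNA-ctrl 4 (0.0524 to 0.0549), and with coarser clusters both were uncalled (0.209 and 0.278).

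In alveolar fibroblast nuclei, Cyp1b1 rose by 5.97 ± 0.40 (edgeR adjusted p 9.5e-06) and Cyp1a1 by 5.15 ± 0.23 (9.4e-08), Galnt15 fell from 42.0 to 10.8 CPM (-1.93 ± 0.25, 0.00122) and Hspb1 by 2.26 on the log2 scale (± 0.43, 0.0186), with all 3 libraries of both groups apart. Cyp1b1 and Cyp1a1 lay at 0.894 and 0.852 times the level expected from free RNA there, so their rises are not separated from it. Nor is the fall of Hspb1, a top 10 gene of low-UMI cluster 0. That cluster held 30.2% of kept barcodes in Nox and 5.01% in LNA-ctrl. Vegfc rose by 1.60 ± 0.20, Sema3c by 1.17 ± 0.14 and Nrp1 by 0.82 ± 0.14 among VEGF and angiogenesis genes (5 of 27 called higher and 1 lower, camera adjusted p 0.00313, 0.659 with estimated correlation). The call of Hspb1 ended without Nox 3, LNA-ctrl 4 or LNA-ctrl 6 (edgeR adjusted p 0.0638 to 0.0891). In all, 602 of 14106 genes were higher and 317 lower. The total of 919 became 596, 413 and 327 without Nox 1, Nox 2 and Nox 3, then 590, 2100 and 494 without LNA-ctrl 4, LNA-ctrl 5 and LNA-ctrl 6, and 612 without LNA-224 8.

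Cyp1a1 and Cyp1b1 were called higher in LNA-ctrl than in Nox in 24 of 24 classes tested and Ahrr in 22 of 24. Tiparp, which is also a target of the aryl hydrocarbon receptor, was called higher in 5 of 24 and not over all nuclei (0.55 ± 0.16). These were aerocyte (2.78), general capillary (2.19), arterial (1.61) and venous endothelial nuclei (1.55) and alveolar macrophages (0.76). Nqo1 was called higher over all nuclei (2.50 ± 0.23, edgeR adjusted p 0.000741) and in 6 of 13 classes. These were the same endothelial classes with AT1 and AT2 nuclei. In the other 19 classes together 9242 class-gene pairs were called, from 81 in myofibroblast nuclei to 974 in monocytes, with 798 in alveolar macrophages, 759 in venous endothelial nuclei and 571 in AT2 nuclei. Without Nox 1, Nox 2, Nox 3, LNA-ctrl 5 and LNA-ctrl 6 the total was 5912, 3989, 4314, 18071 and 5540. Free RNA can carry such calls into classes that do not make the transcript: Chil3, abundant in alveolar macrophages, was called higher in 18 of 24 classes. Of the higher genes, 677 of 706 in monocytes and 495 of 512 in T cells were richer in low-UMI barcodes than in the class. Among all tested genes 44.3 and 46.45% were, and among the lower genes 29 of 268 and 55 of 174. Most higher calls in these classes are thus not separated from free RNA. In venous endothelial nuclei it was 181 of 452 higher genes, against 52.9% of tested genes.

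Across the 6 sets of nuclei and 28 lists, 45 of 155 list tests in LNA-ctrl against Nox passed an adjusted p of 0.05 by camera, 20 up and 25 down, and 0 passed with estimated correlation. Immediate-early and heat-shock genes lay lower in all 6 sets (camera adjusted p 6.5e-08 over all nuclei, 7.2e-10 in aerocytes, 6.1e-07 in arterial and 3.3e-09 in alveolar fibroblast nuclei, each 0.420 with estimated correlation). Hypoxia-induced genes lay higher in arterial nuclei (9 of 28 called higher, camera adjusted p 0.000525, 0.351 with estimated correlation) and aerocytes (5 higher and 1 lower, 0.0116, 0.525) as well as in general capillary nuclei. Interferon-response genes lay lower over all nuclei (0 higher and 10 lower, camera adjusted p 3.4e-06, 0.465 with estimated correlation) and in arterial nuclei (0 and 6, 0.000131, 0.456), where NF-kB genes did too (1 and 7, 0.00121, 0.528). The fall over all nuclei is not separated from composition, as neutrophils went from 5.21 to 0.716% and monocytes from 3.54 to 0.928% of nuclei in named classes. Cell cycle genes lay higher over all nuclei (camera adjusted p 5.9e-05, 0.456 with estimated correlation), where proliferating nuclei went from 0.337 to 0.711% of nuclei in named classes, and so did BMP ligands and receptors (0.0317, 0.732). The clock list lay higher in aerocytes (8 higher and 1 lower of 15, median 0.76, camera adjusted p 0.00522, 0.351 with estimated correlation), where Nr1d2 rose by 2.44 ± 0.22.

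With LNA-224 against LNA-ctrl, 0 of 21303 genes passed an adjusted p of 0.05 over all nuclei by edgeR, while 2972 had an unadjusted p under 0.05 and DESeq2 called 452. No BMP gene was therefore called: Bmpr2 lay at 591 and 515 CPM in LNA-ctrl and LNA-224 (-0.20) and Eng at 94.1 and 114 CPM (0.28, edgeR adjusted p 0.331, although all 3 libraries of each group lay apart), with Id3 at 0.51 ± 0.29, Id1 at 0.38, Smad6 at -0.34 and Smad9 at 0.28. Gabre lay at 0.20 ± 0.15. Some tested genes, 20.1%, separated the groups of 3 and 3 without overlap, against 10% by chance. Without LNA-ctrl 5 the count was 100, without LNA-ctrl 6 it was 39, without LNA-224 7 it was 4, and it was 1 without Nox 2 or LNA-ctrl 4.

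In general capillary nuclei, 3 genes were higher and 13 lower with LNA-224 than with LNA-ctrl. Dbp rose from 3.26 to 13.8 CPM (2.02 ± 0.28, edgeR adjusted p 0.0373), Wars from 79.4 to 158 CPM (0.99 ± 0.15, 0.0375) and Per3 from 16.4 to 32.6 CPM (0.98 ± 0.16, 0.0468), and Ctss fell from 51.5 to 18.3 CPM (-1.49 ± 0.21, 0.0373) and Cacna1c from 277 to 107 CPM (-1.37 ± 0.20, 0.0373), each with all 3 libraries of both groups apart. Cacna1c had risen from 46.1 CPM in Nox. Ctss lay at 20.6% of its LNA-ctrl level in low-UMI barcodes, where it was lower with LNA-224 as well (-0.91), so its fall is not separated from free RNA. Each of these calls ended without Nox 1, Nox 2, Nox 3, LNA-224 8 or LNA-224 9, and that of Ctss also without LNA-ctrl 4 (edgeR adjusted p 0.0516 to 0.188). Bmpr2 (1516 and 1365 CPM, -0.15), Eng (0.16), Id1 (0.54), Id3 (33.8 and 55.6 CPM, 0.70 ± 0.21), Smad6 (-0.38), Smad5 (-0.23), Acvrl1 (0.14) and Gabre (-0.59 ± 0.33) were not called. The count of 16 was 0 without Nox 1, Nox 2, Nox 3, LNA-224 8 or LNA-224 9, and 51, 401, 69 and 97 without LNA-ctrl 4, LNA-ctrl 5, LNA-ctrl 6 and LNA-224 7.

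In aerocyte nuclei, Ahrr fell from 142 ± 12.1 to 32.6 ± 5.69 CPM with LNA-224 (-2.12 ± 0.18, edgeR adjusted p 4.0e-05) and Mir100hg from 51.8 to 15.2 CPM (-1.76 ± 0.24, 0.00599), both with all 3 libraries of each group apart and both called whichever library was left out. In general capillary nuclei Ahrr lay at 213 and 113 CPM, without a call. It was called lower in 3 of 24 classes, the others being venous endothelial (-1.455 ± 0.27, edgeR adjusted p 0.0309) and ciliated nuclei (-1.97 ± 0.44, 0.0488). In ciliated nuclei Ahrr lay at 1.13 times the level expected from free RNA in LNA-ctrl (libraries 0.682 to 1.59). Its fall there is not separated from free RNA. Cyp1b1 was called lower in 1 of 24 classes, aerocytes (195 to 72.6 CPM, -1.41 ± 0.21, edgeR adjusted p 0.00743). Per2 rose from 19.4 to 84.3 CPM (2.11 ± 0.31, edgeR adjusted p 0.0121) and Shisa9 from 36.4 to 112 CPM (1.55 ± 0.28, 0.0498), all 3 libraries again apart. The call of Per2 ended without LNA-ctrl 4, LNA-224 8 or LNA-224 9 (edgeR adjusted p 0.0569 to 0.0854) and that of Shisa9 without Nox 2, LNA-ctrl 5, LNA-224 7 or LNA-224 9 (0.05002 to 0.208). In all, 11 genes were higher and 16 lower. The total of 27 was 17 without Nox 2, 131 without LNA-ctrl 5, 54 without LNA-ctrl 6, and 67, 7 and 8 without LNA-224 7, LNA-224 8 and LNA-224 9.

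In arterial nuclei, Inf2 rose by 1.42 ± 0.26 with LNA-224 (edgeR adjusted p 0.0151), and the clock genes Npas2 (26.3 to 6.62 CPM, -1.995 ± 0.30, 0.00559) and Arntl (81.0 to 24.6 CPM, -1.67 ± 0.23, 0.00445) fell, all 3 genes with the 3 libraries of each group apart. Inf2 was not called without LNA-224 7 or LNA-224 9 (edgeR adjusted p 0.0540 to 0.131), Npas2 without LNA-224 8 or LNA-224 9 (0.0515 to 0.0721) or Arntl without LNA-224 9 (0.0565). In all, 12 genes were higher and 41 lower. The total of 53 was 28 without Nox 1, 27 without Nox 2, 30 without LNA-ctrl 4, 85 without LNA-ctrl 5, 112 without LNA-ctrl 6, and 28, 6 and 2 without LNA-224 7, LNA-224 8 and LNA-224 9.

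In smooth muscle nuclei, 2 genes were called with LNA-224, both lower: Npas2 (90.2 to 22.1 CPM, -2.03 ± 0.25, edgeR adjusted p 0.00186) and Spp1 (41.7 ± 31.0 to 2.44 CPM, -3.80 ± 0.60, 0.0278), with all 3 libraries of each group apart. Spp1 lay at 14.6% of its LNA-ctrl level in low-UMI barcodes, where it was lower with LNA-224 as well (-3.64), so its fall is not separated from free RNA. Npas2 was not called without LNA-224 8 (edgeR adjusted p 0.0516), and Spp1 was not called without Nox 2, LNA-ctrl 4, LNA-224 7, LNA-224 8 or LNA-224 9 (0.0507 to 0.300). The count was 7 without Nox 1, 24 without LNA-ctrl 5, 5 without LNA-ctrl 6, 0 without LNA-224 8 and 1 without Nox 2, LNA-ctrl 4 or LNA-224 9.

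In alveolar fibroblast nuclei, Galnt15, which was lower in LNA-ctrl than in Nox, rose from 10.8 to 38.0 CPM with LNA-224 (1.78 ± 0.25, edgeR adjusted p 0.0184) and Per2 from 12.4 to 42.8 CPM (1.75 ± 0.26, 0.0210). Npas2 fell from 55.7 to 8.45 CPM (-2.71 ± 0.35, 0.0184) and the sterol gene Fdft1 from 39.98 to 12.1 CPM (-1.72 ± 0.24, 0.0184), all 4 genes with the 3 libraries of each group apart. Every one of these 4 calls ended without LNA-224 8 or LNA-224 9, those of Npas2 and Per2 also without LNA-ctrl 4, and that of Per2 without Nox 2 as well (edgeR adjusted p 0.0510 to 0.111). In all, 19 genes were higher and 47 lower. The total of 66 was 24, 16 and 29 without Nox 1, Nox 2 and Nox 3, 33 without LNA-ctrl 4, 226 without LNA-ctrl 5, and 25, 0 and 1 without LNA-224 7, LNA-224 8 and LNA-224 9.

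The other 19 classes gave 1378 class-gene pairs with LNA-224 against LNA-ctrl, of which T cells (42 higher, 331 lower), mesothelial nuclei (78 and 145), monocytes (24 and 198), ciliated epithelial nuclei (62 and 75) and alveolar macrophages (11 and 92) held most. The total was 7066 without LNA-ctrl 5 and 741, 577 and 259 without LNA-224 7, LNA-224 8 and LNA-224 9. Some lower genes recur in unrelated classes: Chil3 was called lower in 14 of 24 classes. Alveolar macrophages, where it is abundant, are among them, with 2202, 5353 and 2203 CPM in Nox, LNA-ctrl and LNA-224. There the fall with LNA-224 had an edgeR adjusted p of 0.0443. Of the genes lower with LNA-224, 12 of 13 in general capillary, 14 of 16 in aerocyte, 30 of 41 in arterial, 1 of 2 in smooth muscle and 28 of 47 in alveolar fibroblast nuclei were richer in low-UMI barcodes than in the class, against 49.7 to 60.4% of tested genes.

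Circadian clock genes differed between the Su/Hx groups in many classes. Dbp was called higher with LNA-224 in 10 of 14 classes tested, Per2 in 8 of 21, Tef in 8 of 24, Per3 in 7 of 21, Nr1d1 in 4 of 18, Hlf in 3 of 13 and Per1 in 1 of 23, and Npas2 was called lower in 11 of 21, Arntl in 7 of 24 and Lonrf3 in 1 of 17. As a list, clock genes moved up in all 6 sets of nuclei, with camera adjusted p-values of 0.0115 over all nuclei (median 0.42), 0.00239 in general capillary (0.64), 4.3e-06 in aerocyte (0.97), 0.0398 in arterial (0.53), 0.0140 in smooth muscle (0.66) and 0.00401 in alveolar fibroblast nuclei (0.42). With estimated correlation these were 0.473, 0.446, 0.191, 0.531, 0.468 and 0.446. Adjusted over the list alone, 9 were higher and 2 lower of 15 in aerocytes and 9 higher and 4 lower of 18 in alveolar fibroblasts. In alveolar fibroblasts Dbp rose from 6.61 to 26.7 CPM (1.98 ± 0.22, edgeR adjusted p 0.00742, all 3 libraries apart), not called without LNA-224 8 (0.0570), and in aerocytes Tef rose by 1.14 ± 0.17, also not called without LNA-224 8 (0.0642). Clock genes differed from Nox as well. With LNA-224 against Nox, Dbp was called higher in 12 of 14 classes and Nr1d2 in 16 of 24, both lower in 0. Npas2 was called lower in 15 of 21 and Arntl in 13 of 24, both higher in 0. With LNA-ctrl against Nox, Dbp was called higher in 5 and Nr1d2 in 9, both lower in 0. Npas2 was called lower in 3 and higher in 1, and Arntl lower in 4 and higher in 1. The time of day at which lungs were taken is not given in the sources used here.

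**Figure D2:**
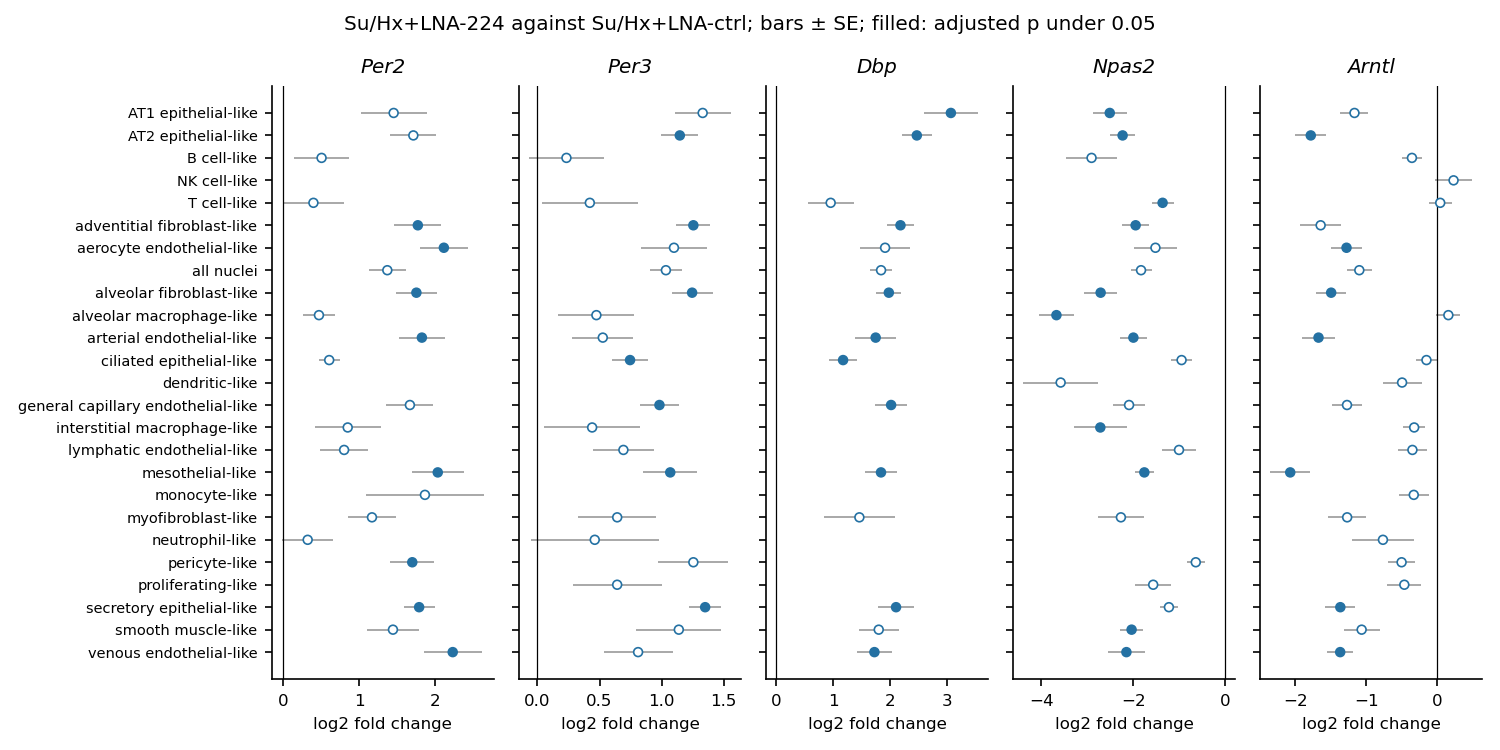
Log2 fold change of 5 clock genes in LNA-224 against LNA-ctrl (n = 3 each) by class of nuclei and over all nuclei, bars ± SE, filled points for an edgeR adjusted p under 0.05. Dbp lies above 0 in 14 of 14 classes and Npas2 below 0 in 21 of 21.

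Of 155 list tests between LNA-224 and LNA-ctrl, 46 passed an adjusted p of 0.05 by camera, 27 up and 19 down with the clock list among them, and 0 passed with estimated correlation. In general capillary nuclei, antigen presentation genes lay higher (0 of 16 called, 6 higher adjusted over the list alone, median 0.49, camera adjusted p 4.3e-07, 0.625 with estimated correlation) and BMP ligands and receptors lower (0 of 22 called, 4 lower adjusted over the list alone, median -0.25, 0.00339, 0.656 with estimated correlation). BMP-SMAD targets had a median of 0.16 there (camera adjusted p 0.321), hypoxia-induced genes 0.11 (0.440) and reported miR-224 targets 0.01 (0.718). Over all nuclei, cell cycle genes lay lower (0 of 30 called, median -0.38, camera adjusted p 1.6e-10, 0.446 with estimated correlation), while proliferating nuclei went from 0.711 to 0.439% of nuclei in named classes, and SMAD transducers too (0 of 14 called, median -0.21, 0.0435, 0.776 with estimated correlation). Glucocorticoid response genes lay higher in all 6 sets, with 0 called in alveolar fibroblasts (median 0.68, camera adjusted p 9.3e-05, 0.686 with estimated correlation). Contractile genes, which were lower in LNA-ctrl smooth muscle nuclei, lay higher with LNA-224 (0 of 20 called, median 0.27, camera adjusted p 0.00310, 0.686 with estimated correlation), Cnn1 being at 77.7 and 128 CPM.

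Over all nuclei 78.7% of the 1302 changed genes had the opposite sign in LNA-224 against LNA-ctrl, and in general capillary nuclei 68.6% of 1705 did. Some of this follows from the shared LNA-ctrl group, since simulations without any LNA-224 effect gave a median of 65.4% (63.3 to 67.6) and 63.4% (61.4 to 65.6), and 0 of 100 simulations reached the real value in either set. Without Nox 3, LNA-ctrl 4, LNA-ctrl 5 or LNA-ctrl 6 the share over all nuclei was 71.6%, 73.3%, 91.4% and 83.1%, and in general capillary nuclei 61.7%, 60.5%, 81.3% and 72.2%. Of 20 assignments of the libraries, 3 gave a share at least as high over all nuclei and 7 in general capillary nuclei, so a return of these genes towards Nox with LNA-224 is not shown beyond chance. In general capillary nuclei 10 genes were called in both comparisons, Cacna1c among them. Of these, 6 had opposite signs, all 6 higher in LNA-ctrl and then lower with LNA-224.

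Genes with a miR-224 seed site in their 3' UTR were compared with matched genes without one, 2014 in each set. Their mean log2 change with LNA-224 against LNA-ctrl was -0.03 relative to the matched genes (exact permutation p 0.1, the smallest that 3 and 3 libraries can give), the direction opposite to release from miR-224. The counts are of nuclear RNA, and how far release from a miRNA shows there was not tested. Relative levels were 0.02 to 0.03 in LNA-ctrl 4 to 6, -0.01, 0.01 and -0.01 in LNA-224 7 to 9 and 0.01 in each Nox library. In general capillary nuclei the difference was -0.01. The 429 genes with an 8-base site gave 0.01, and a camera test of the sites gave p 0.384 (0.703 with estimated correlation). The mature miR-224 itself was not measured, Mir224 being absent from the counted genes.

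LNA-224 against Nox left 347 genes higher and 426 lower over all nuclei and 868 higher and 763 lower in general capillary nuclei. Cyp1a1 and Cyp1b1 stayed higher than Nox in 24 of 24 classes and Ahrr in 19. Only in aerocyte and venous endothelial nuclei did Cyp1a1 exceed its level in low-UMI barcodes in every LNA-224 library. Cyp1b1 did so only in arterial, general capillary, venous endothelial and secretory nuclei. Calls of both genes in many other classes are thus not separated from free RNA. The total of 773 over all nuclei was 364 without Nox 1, 324 without Nox 2, 1425 without LNA-ctrl 4, and 451, 277 and 297 without LNA-224 7, LNA-224 8 and LNA-224 9, and the 1631 in general capillary nuclei were 970 without Nox 2, 1012 without LNA-224 8 and 987 without LNA-224 9.

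The shares of 9 of 27 classes differed among the 3 groups (exact permutation test over 280 assignments, Benjamini-Hochberg). As percent of nuclei in named classes (mean ± SD, n = 3 libraries in Nox, LNA-ctrl and LNA-224), aerocytes were 3.84 ± 0.111, 2.97 ± 0.137 and 2.48 ± 0.146, lymphatic endothelial nuclei 0.784 ± 0.0790, 1.76 ± 0.427 and 2.35 ± 0.171, neutrophils 5.21 ± 2.11, 0.716 ± 0.236 and 1.72 ± 0.513, T cells 2.58 ± 0.0538, 2.44 ± 0.128 and 3.50 ± 0.6002, and proliferating nuclei 0.337 ± 0.0460, 0.711 ± 0.136 and 0.439 ± 0.0978, each with an adjusted exact p of 0.0193. Alveolar macrophages were 2.44 ± 0.391, 5.26 ± 1.22 and 3.77 ± 0.403 and smooth muscle nuclei 0.512 ± 0.111, 0.960 ± 0.0784 and 1.11 ± 0.114 (both adjusted exact p 0.0276), alveolar fibroblasts 7.99 ± 0.327, 7.25 ± 0.755 and 6.09 ± 0.206 (0.0362) and NK cells 1.22 ± 0.361, 0.728 ± 0.133 and 0.536 ± 0.0677 (0.0429). Monocytes (3.54, 0.928 and 1.03%, adjusted exact p 0.0579), arterial (2.84, 2.17 and 2.78%, 0.0643) and general capillary nuclei (19.6, 20.2 and 20.3%, 0.911) were not called. Shares are relative, so a fall of neutrophils raises the others, and they measure nuclei released, not cells present. The number of classes called was 4 without Nox 1, Nox 2 or LNA-ctrl 6 and 2 without LNA-ctrl 4. It was 3 as percent of all kept barcodes and 0 without Nox 3 and LNA-ctrl 5 together.

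**Figure D3:**
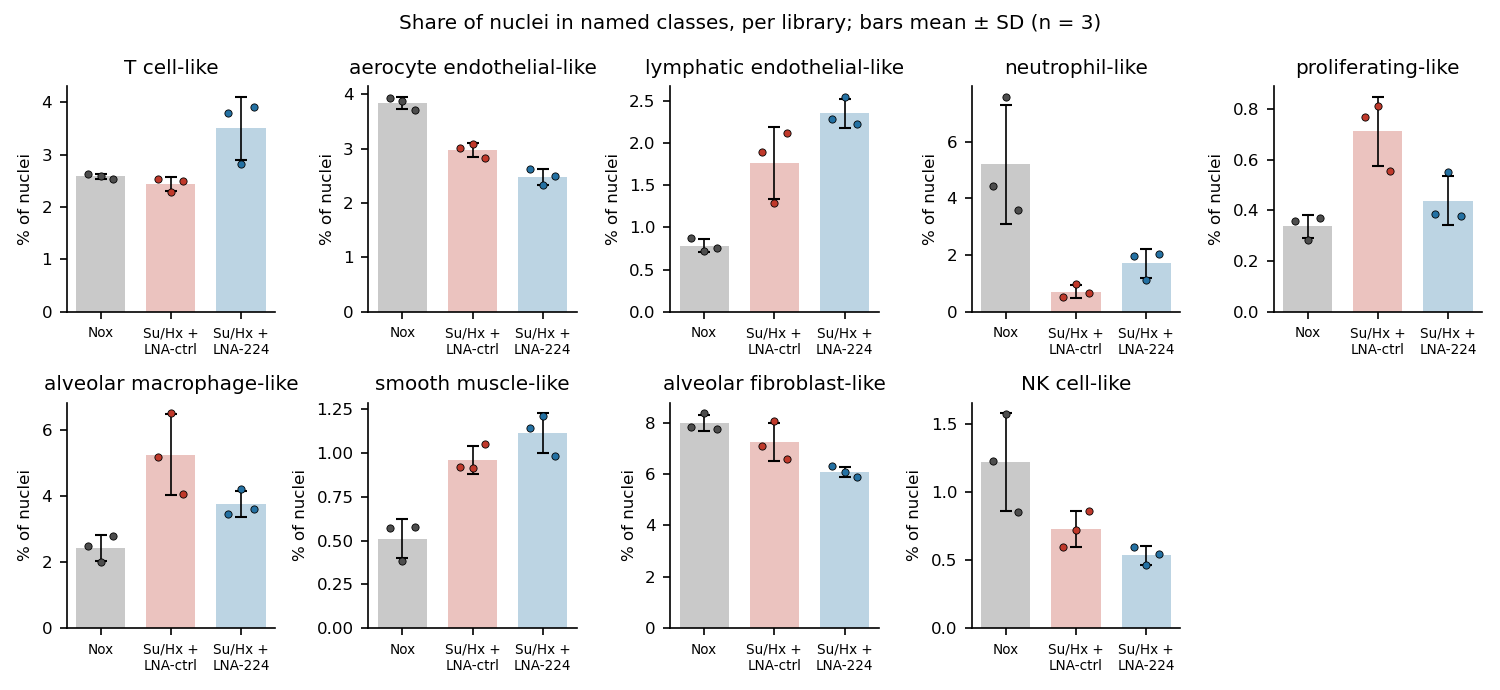
Share of nuclei in named classes (percent) for the 9 classes called, by group (Nox, LNA-ctrl, LNA-224), with points for libraries and bars for mean ± SD (n = 3). Aerocytes lie at 3.84, 2.97 and 2.48% and neutrophils at 5.21, 0.716 and 1.72% on average.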

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

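The tests of explanations in this part, all of which concern the 3 patterns below, and the splits of libraries were chosen after the results were seen.

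Changes between the groups differed between the 2 capillary classes for some genes when the difference itself was tested. The test was limma on the per-library difference of log2 CPM between the classes (11005 genes, 3 libraries per group). In LNA-ctrl against Nox 882 genes differed, 380 of them with the higher effect in aerocytes. Apba1 gave a difference of -2.09 on the log2 scale (0.67 in aerocytes, 2.76 in general capillary nuclei), Igf1r 1.39 (0.79 and -0.61), Myo10 1.54 (0.62 and -0.92) and Kcnc2 5.98 (5.41 and -2.07). The class effects in brackets come from the separate edgeR fits. For Kcnc2 they lie further apart than the tested difference. With LNA-224 against LNA-ctrl 104 genes differed, 75 with the higher effect in aerocytes: Scn3b by 1 (0.87 in aerocytes and -0.11 in general capillary nuclei), Pde8b by 1.04, Prdm1 by 1.07 and Kdr by 0.673 (0.03 in aerocytes and -0.63 in general capillary nuclei). Leaving out 1 library gave 643 to 917 genes for LNA-ctrl against Nox. For LNA-224 against LNA-ctrl it gave 30 to 136, with 69 without LNA-ctrl 4, 54 without LNA-224 8 and 30 without LNA-224 9. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The highest other splits gave 0 against 882 (1 of 10 as large) and 2 against 104 (1 of 10).

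Barcodes outside the comparisons of classes carry the genes with the strongest rises in LNA-ctrl against Nox. In low-UMI barcodes Ahrr lay at 45.3 CPM in LNA-ctrl against 0.572 in Nox, Cyp1a1 at 334 (333.5) against 7.18, and Cyp1b1 at 270 (269.9) against 5.46. Whether these barcodes hold free RNA, damaged nuclei or debris was not tested. In LNA-ctrl most of them lie in another cluster (32.5% of barcodes in cluster 1) than in Nox and LNA-224 (0.410 and 1.08%). The pattern was weighed against a response of blood endothelial cells. In the 4 blood endothelial classes the lowest ratio of the level to that expected from free RNA, over 3 genes and 3 LNA-ctrl libraries, was 2.29 (2.285), and the highest class ratio 21.2, which argues against free RNA as the source there. Ratios in general capillary nuclei were 19.3 for Ahrr, 4.38 for Cyp1a1 and 6.20 for Cyp1b1. All 12 of 12 class-gene pairs were called higher in both Su/Hx groups than in Nox, but this restates the pattern and decides nothing about a response of these cells to the Su/Hx treatment, which stays open. In 18 other classes the median ratio for Cyp1a1 was 0.870 (0.8699, range 0.685 to 1.37), so free RNA may account for the Cyp1a1 calls in these classes. This does not extend to Ahrr, which lay above 1.5 times the expected level in every LNA-ctrl library in 8 of the 18, with ratios of 19.5 in interstitial macrophages (271 against 13.9 CPM expected), 13.4 in lymphatic endothelial and 10.98 in dendritic nuclei. Nor does it extend to Cyp1b1 in proliferating nuclei, with a ratio of 2.185 (lowest library 1.83). AT2 and secretory nuclei are not among the 18, and Cyp1b1 lay at 408 CPM in secretory nuclei, 151% of its level in low-UMI barcodes. Since the labels give Su/Hx as one treatment, an effect of sugen and one of hypoxia cannot be separated here. Both Su/Hx groups also carry an LNA and the Nox label names none, so an effect of the oligonucleotide cannot be separated either.

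Genes lower with LNA-224 than with LNA-ctrl in T cells and monocytes form the next pattern. Of 529 lower genes 520 (98.3%) were richer in low-UMI barcodes than in the class, against 45.5% of all tested genes and 15 of the 66 higher genes. Free RNA may thus be the source of most of these differences. The feature is not particular to LNA-224, since 495 of 512 genes higher in LNA-ctrl than in Nox in T cells and 677 of 706 in monocytes shared it. Whether LNA-224 also acts within these cells cannot be told apart from it: of 595 calls in the 2 classes 7 were left once genes richer in low-UMI barcodes were not tested. Since 15 of the 66 higher genes were richer, this drop also holds calls of genes that stayed in the test. The new fit changed their spread and adjusted p, so the 7 do not count the calls free of free RNA.

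The clock genes are the other pattern. Over all classes there were 60 class-gene calls between LNA-224 and LNA-ctrl, 41 higher and 19 lower, in 16 classes and 10 genes. Free RNA was tested in 2 ways. By the first, 32 of 60 calls had a level above that of low-UMI barcodes, which decided nothing. By the next, set after the first had been computed, 48 of 49 changes compared were larger than the whole level expected from free RNA, which argues against free RNA as the source. The fold change of Dbp lay above 0 in 14 of 14 classes and that of Npas2 below 0 in 21 of 21. This is what a difference in the time of day of collection would give, and also what an effect of LNA-224 on the clock would give. Clock genes also differed between LNA-ctrl and Nox, a comparison without LNA-224, which does not decide between these explanations. The explanations cannot be told apart, because no time of collection is given and each group may have been collected together.

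For each count of changed genes the 10 splits of 3 against 3 libraries are too few for a share under 0.05. In LNA-ctrl against Nox the highest other split gave 0 genes against 1302 over all nuclei, 1705 in general capillary, 813 in aerocyte, 1249 in arterial, 280 in smooth muscle and 919 in alveolar fibroblast nuclei (each 1 of 10 as large), and 4 against 9242 class-gene pairs. In LNA-224 against LNA-ctrl it gave 3 against 0 over all nuclei (10 of 10 as large), 4 against 16 in general capillary, 0 against 27, 53 and 2 in aerocyte, arterial and smooth muscle nuclei, 2 against 66 in alveolar fibroblasts and 12 against 1378 pairs. In LNA-224 against Nox it gave 0 against 773 and 1631. For gene lists another split gave 51 against 45 in LNA-ctrl against Nox (2 of 10 as large), and 33 against 46 in LNA-224 against LNA-ctrl. Of 20 assignments, 3 gave an opposite-sign share at least as high as 78.7% over all nuclei (highest other 84.6%) and 7 as high as 68.6% in general capillary nuclei (73.2%), so chance is not excluded for these shares.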

How the results depend on the processing

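Leaving out genes richer in low-UMI barcodes, using named classes only, leaving out Nox 3 and LNA-ctrl 5 together (the 2 libraries whose doublets were not called by the automatic threshold), all kept barcodes as denominator and the library omissions for capillary differences were chosen after the data were seen. Values follow the order all nuclei, general capillary, aerocyte, arterial, smooth muscle and alveolar fibroblast nuclei unless named. No paired analysis was possible because the groups share no replicate numbers. The cause was not tested unless given.

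DESeq2 gave 2597 genes over all nuclei for LNA-ctrl against Nox (1302 by edgeR), and 1553 for LNA-224 against Nox (773). For LNA-224 against LNA-ctrl it gave 452, 619, 132, 120.0, 11 and 232 genes and 4430 pairs in the remaining classes (0, 16, 27, 53, 2, 66 and 1378 by edgeR), with 201 of 619 higher in general capillary (3 of 16) and 95 of 232 in alveolar fibroblast nuclei (19 of 66). A fit of 2 groups only, with fewer libraries behind each spread, gave 560.0, 128 and 409 over all, smooth muscle and alveolar fibroblast nuclei for LNA-ctrl against Nox (1302, 280 and 919), 1589 over all nuclei for LNA-224 against Nox, and 0, 15, 24, 26 and 2 in the 5 classes and 792 pairs for LNA-224 against LNA-ctrl. Without the low-count filter LNA-ctrl against Nox gave 1269 in aerocytes, 592 in smooth muscle and 17558 pairs, and LNA-224 against LNA-ctrl 3, 196, 421, 384, 138 and 218 and 7248 pairs.

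With doublets kept LNA-224 against LNA-ctrl gave 1 gene over all nuclei, 4 in general capillary and 20 in alveolar fibroblast nuclei and 208 pairs. Leaving out markers of other classes gave 8 genes in general capillary nuclei, and Leiden resolution 0.8 gave 16 in smooth muscle. Leaving out genes richer in low-UMI barcodes, which tests fewer genes, gave 1077, 513 and 514 in general capillary, aerocyte and alveolar fibroblast nuclei and 4473 pairs for LNA-ctrl against Nox, and 0, 6, 9, 1 and 18 in the 5 classes and 110 pairs for LNA-224 against LNA-ctrl. Leaving out Nox 3 and LNA-ctrl 5 gave 817 arterial genes for LNA-ctrl against Nox, 33, 266, 144, 85, 55 and 280 genes and 6717 pairs for LNA-224 against LNA-ctrl, opposite-sign shares of 85.3% over all and 73.3% in general capillary nuclei, and 0 classes with a changed share. RLE size factors, at least 1000 UMIs and named classes only moved no count by over 1.5 times.

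With estimated correlation 0 lists moved in either comparison (45 and 46 with the preset correlation), and fry moved 20 and 6. The 500 lowest p gave opposite-sign shares of 76.0% over all and 60.8% in general capillary nuclei. All kept barcodes as denominator gave 3 classes with a changed share instead of 9. The seed-site value reversed with 8-base sites (0.0108 against -0.0266) and was -0.1134 against unmatched genes, whose 3' UTRs are shorter (median 671 against 2433 bases). Lamp3 (-0.0156 against 1.16) and Slc34a2 (-0.13 against 0.84), surfactant genes called higher in LNA-ctrl arterial nuclei, reversed with doublets kept.

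Leaving out 1 library gave, for LNA-ctrl against Nox, 516 to 3128 genes over all nuclei, 992 to 2379 in general capillary, 456 to 980 in aerocyte, 842 to 1191 in arterial, 124 to 357 in smooth muscle and 327 to 2100 in alveolar fibroblast nuclei, and 3989 to 18071 pairs. For LNA-224 against LNA-ctrl it gave 0 to 100, 0 to 401, 7 to 131, 2 to 112, 0 to 24 and 0 to 226 genes and 259 to 7066 pairs, and for LNA-224 against Nox 277 to 1425 over all and 970 to 2379 in general capillary nuclei. Lists moved ranged over 42 to 51 and 38 to 50, opposite-sign shares over 71.6 to 91.4% and 60.5 to 81.3%, changed class shares over 2 to 7 and the seed-site value over -0.03 to -0.02. The highest gene counts for LNA-224 against LNA-ctrl came without LNA-ctrl 5, except in arterial nuclei (LNA-ctrl 6).

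Of 9986 values of 556 named-gene results under the alternatives, 9079 kept direction and side of the threshold, 517 kept direction and lost the call, 344 gained one, 2 reversed and 44 uncalled values changed sign. Of 1131 values of class shares 94 moved by over 1 SD, and of 18 counts of capillary differences 3 moved. Smooth muscle nuclei are few, and there 24.5% of simulated 2-fold changes were found.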

Other observations

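Values that belong to no comparison are given here, together with tests named above, which were chosen after the results were seen. The surfactant genes in T cells lay at 26.7 ± 6.88% of their level in low-UMI barcodes in Nox, 35.5 ± 7.41% in LNA-ctrl and 23.1 ± 0.837% in LNA-224 (mean ± SD, n = 3). Kdm5d lay at 55.8 to 62.2 CPM and Uty at 195 to 269 CPM in the 9 libraries. In low-UMI barcodes 387 genes were higher and 153 lower with LNA-224 than with LNA-ctrl by edgeR, and the 2 groups' barcodes lie mostly in different clusters (cluster 1 holds 32.5% of LNA-ctrl and 1.08% of LNA-224 barcodes).

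The opposite signs of the 2 comparisons also show in the covariance of the 2 sets of log2 fold changes, which was -0.143 over all nuclei (simulated without a change -0.0425, range -0.0478 to -0.0374) and -0.127 in general capillary nuclei (-0.0442). It exceeds what the shared LNA-ctrl group gives in these simulations. The 3 control libraries cannot be divided between the 2 comparisons, and the simulations assume that libraries of a group vary alike. The LNA-ctrl libraries may not do so: chi-square per degree of freedom was 311 and 225 for LNA-ctrl 4 with 5 and 6, and 103 for 5 with 6. With 1 library left out the opposite-sign share over all nuclei ranged from 71.6% (without Nox 3) to 91.4% (without LNA-ctrl 5). Without Nox 3 and LNA-ctrl 5 together it was 85.3%.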
